A study of Mus musculus with 32 samples.

How the data were processed

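Gene expression was measured with Affymetrix Mouse Genome 430 2.0 arrays in liver of CD-1 mice. Of 32 arrays, 2 came from unoperated 10-week-old females (time 0), 18 from liver after removal of 2/3 of the organ (1, 2 and 6 h, then 12, 18, 24 and 30 h, then 48 and 72 h), and 12 from embryonic liver, at daily steps from 10.5 to 14.5 days and at 16.5 days. Each array took 6 microg of Trizol-extracted total RNA, labelled as biotinylated cRNA, from a pool of at least 3 tissues of different animals. The groups were read from the source name of each sample, which gives the same stages as the titles. In the embryonic samples other label fields conflict with it (an age of 10.5 days for all 12, and a description of adult female liver), and those fields were not used.

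The deposited values are a probe set intensity per array on a linear scale. The software, background treatment and normalization behind them are not given in the sources used here. Array medians ran from 69.7 to 79.5, the 75th percentiles spanned 0.343 on the log2 scale, and between 2.54% and 4.02% of the values of an array were below 0. Because that span was under the limit of 1 set in advance, the deposited normalization was kept. Values below 0 were set to 0, and log2(value + 16) was analysed; levels are given as deposited.

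Of 45101 probe sets, 35890 were listed with a gene and 932 of these with several, which left 34958 with 1 gene and 18194 genes. For the 9012 genes with more than 1 probe set, the probe set of highest mean was used. Of the 9211 probe sets without a listed gene, the 9160 that are not control probe sets of the array were tested on their own and are given only as counts. No symbol was changed through the reference table (0 changes). Ccnb1, H19 and Hbb-b1, which were to be named in any case, are not analysed here.

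Comparisons, tests, alternatives and 29 gene lists were set before the data were examined, as were the phases 1 to 6 h, 12 to 30 h and 48 to 72 h. R 4.3.3 and limma 3.58.1 fitted 1 mean per group to all 32 arrays (16 residual degrees of freedom, 4.76 prior degrees of freedom) with eBayes(trend = TRUE). The contrasts were each of 9 times and each of 3 phases against time 0, the mean of the 6 embryonic stages against time 0 and against 48 to 72 h, and the linear change per day over the stages. P-values were adjusted by Benjamini-Hochberg within a contrast and called at 0.05. Moderated F tests were run over the 9 times and over the 6 stages.

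Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 29 lists of a contrast (174 tests in 6 contrasts), and members were also adjusted over the list alone. The lists were immediate early; acute phase; DNA replication and S phase; mitosis; p53 targets; ribosome biogenesis; heat shock and unfolded protein response; drug and steroid cytochrome P450; urea cycle and amino acid catabolism; bile acid synthesis and transport; gluconeogenesis and glycogen; cholesterol synthesis; fatty acid oxidation and ketogenesis; fatty acid synthesis; secreted plasma proteins of the hepatocyte; liver transcription factors; hepatoblast and fetal liver; embryonic globins; erythroid; blood progenitors, neutrophils and megakaryocytes; macrophages and Kupffer cells; lymphocytes; endothelium; stellate cells and mesenchyme; bile duct epithelium; neighbouring organs; circadian clock; extracellular matrix remodelling and growth factors; and sex chromosome linked expression. They hold 585 genes, of which 534 were measured. Of the measured members, 3 liver transcription factors and 1 member each of the bile acid, fatty acid oxidation and bile duct lists are also in another list, and 0 of the other lists.

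Genes were named by a fixed rule. It took the 8 largest rises and falls of each of the 6 main contrasts, up to 4 members of smallest p per list and contrast, 3 rises and 3 falls per single time, 8 genes each of those raised and those lowered both late and in the embryo, and 5 of each opposite kind. The first set needed all replicates on the same side and a higher group mean above the median of all values (74.6). Not every gene the rule gives is named, and genes whose call depended on few settings were preferred; other genes come from a list of known liver genes set in advance. Genes shared by 2 contrasts against time 0 were set against the number that independent lists would share and against 20 simulated draws of unchanged groups with the shared controls. The correlation with the developmental trend was tested by exact permutation of the 6 stages. Random draws used seed 11.

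The fit was tested on simulated data with known changes. At 2-fold it recovered 74.6% of changed genes at 1 to 6 h, 73.1% at 12 to 30 h, 62.7% at 48 to 72 h, 65.7% in the embryo against time 0, 55.2% in the trend and 83.6% in the embryo against 48 to 72 h. At 1.5-fold it recovered 20.9% to 47.8% and at 4-fold 93.9% to 100%. Between 5 and 15 of 17994 unchanged genes were called. The simulated noise was independent between genes and had the same SD in every group. In the data the SD of the difference between the arrays of a group ran from 0.284 at 2 h to 0.741 at 48 h. These rates therefore need not hold for comparisons that use the noisier groups. Each simulated set also left 17994 of 18194 genes unchanged. In the data 55.1% of genes were called in the embryo against time 0, 66.1% in the embryo against 48 to 72 h and 27.6% in the trend. Adjusted p-values depend on that share, so the rates need not hold for those comparisons either.

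The alternatives were an added constant of 1 or 64; quantile normalization; array median centring; only genes in the upper 50% by mean; the mean of probe sets; no probe sets whose names end in _x_at or _s_at; eBayes without a trend; only the groups compared; calls at 2-fold or more; replicate number as a block; each array left out; camera with an estimated correlation; fry; and the correlation without 10.5 days. The second arrays of 12 h and 48 h left out together, and array weights, were added after the data had been seen. No group has enough arrays for an outlier test, and no array was left out of the values given. Figures were drawn with matplotlib 3.10.9.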

Results

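Mouse liver was measured on 32 arrays: unoperated liver of 10-week-old females (time 0), liver at 9 times from 1 to 72 h after partial hepatectomy, and embryonic liver at 6 stages from 10.5 to 16.5 days post conception. No sham-operated group is among them. Changes after hepatectomy therefore cannot be divided between the operation itself and the loss of liver tissue. Each of the 16 groups has 2 arrays, and each array holds a pool of at least 3 tissues. The labels say no more of the samples than that they are separate pools, so p-values measure the spread between such samples. In the fit of all 32 arrays that spread was estimated for each gene over all 16 groups, not from the arrays compared alone. The arrays of 48 h differed most from each other, so errors there may be understated, and those of more even groups overstated. The 2 arrays a group limit the precision of every value. Folds and log2 changes refer to log2(value + 16), which understates the change of genes with low values. A ± after a level is the SD of 2 arrays, and a ± after a log2 change is its standard error. Genes were called at an adjusted p under 0.05 among 18194 genes, and "raised" and "lowered" refer to called genes. Beside the counts of a gene list, p-values are adjusted p-values of camera, also where only the value is given.

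Adult and embryonic arrays stood furthest apart. Cyp2e1, a cytochrome P450 of mature hepatocytes, averaged 6140 ± 1200 at time 0 and lay between 53.42 and 86.18 at the embryonic stages. In contrast Afp, the fetal counterpart of albumin, lay between 2683 and 4522 in the embryo and averaged 53.23 ± 6.66 at time 0. The first principal component held 72.8% of the variance and placed all 20 adult arrays on one side of 0 and all 12 embryonic arrays on the other. The second component (6.91%) was highest on the arrays of 10.5 days (0.544 and 0.363), the second array of 48 h (0.41) and the second of 12 h (0.268).

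The arrays of 48 h stood apart from each other in cell cycle and hepatocyte genes. On the second of them Mki67, a marker of cycling cells, read 175 against 25 on the first, Top2a 250 against 47 and Cdk1 316 against 53, and the median of the mitosis list was 1.30 (log2) higher. In the same array the medians of the acute phase list (-1.24), the drug and steroid cytochrome P450 list (-0.95) and the secreted plasma proteins (-1.15) were lower than in the first. Its 3 prime over 5 prime log2 ratios were 2.5 for Actb and 1.25 for Gapdh, against means of 0.97 (SD 0.33) and -0.23 (SD 0.24) on the other 19 adult arrays. The Gapdh ratio was highest of all 32 on the first array of 10.5 days (1.49, against -0.43 to -0.17 on the other 11 embryonic arrays), and Actb and Gapdh ratios were 1.74 and 0.32 on the second array of 2 h and 1.40 and 0.30 on the second of 12 h. The SD of the difference between the arrays of a group was 0.741 at 48 h, 0.534 at 10.5 days, 0.497 at 12 h and 0.284 to 0.433 elsewhere.

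Igfbp1, G6pc and Jun were among the genes raised at 1 h, Lcn2 and Cd14 among those raised at 12 h, and Cdk1 and Birc5 among those raised at 72 h. Cd14, a receptor for bacterial lipopolysaccharide, rose by 4.83 ± 0.38 (log2, n = 2 against 2, adjusted p = 2.2e-07) at 12 h, and Saa3 by 5.43 at 18 h. Nrep was lowered at 18 h (-4.89 ± 0.40), but by only -1.16 once ambiguous probe sets (name ending in _x_at or _s_at) were left out. The counts of raised and lowered genes were 72 and 14 at 1 h, 76 and 23 at 2 h, 184 and 176 at 6 h, 761 and 832 at 12 h and 802 and 589 at 18 h. Later they were 111 and 102 at 24 h, 42 and 16 at 30 h, 110 and 150 at 48 h, and 475 and 54 at 72 h. A moderated F test over the 9 times called 3217 genes (17.7%), of which 924 had their largest change at 12 h, 820 at 18 h and 436 at 72 h. Of the last, 416 were higher than at time 0.

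The totals at single times leaned on single arrays. Without the first array of time 0 the totals were 179 at 6 h, 961 at 12 h, 921 at 18 h, 98 at 24 h, 35 at 30 h and 136 at 48 h. Without the second they were 936 at 12 h, 708 at 18 h, 105 at 48 h and 320 at 72 h. Without an array of the time itself they were 45 at 1 h (second array), 56 and 47 at 2 h, 142 at 6 h (first), 757 at 12 h (second), 581 at 18 h (second), 359 and 36 at 24 h, 18 and 18 at 30 h, and 274 and 219 at 72 h. Without the first array of 48 h the total at 48 h was 3210 (636 raised, 2574 lowered), with 174 at 1 h, 431 at 24 h, 139 at 30 h and 834 at 72 h. Without the second, 174, 431 and 139 were called at the first 3 of those times and 833 at 72 h. In limma fits of only the 4 arrays compared, 2 genes were called at 12 h, 27 at 18 h and 46 at 72 h. Those limma fits called 0 genes at 1, 2, 6, 24, 30 and 48 h, where 1343, 1375, 1727, 1518, 1512 and 607 genes had an unadjusted p under 0.05. Array weights, added after the data had been seen, left 1 gene called at 48 h and gave 886 at 12 h and 130 at 30 h.

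**Figure D1:**
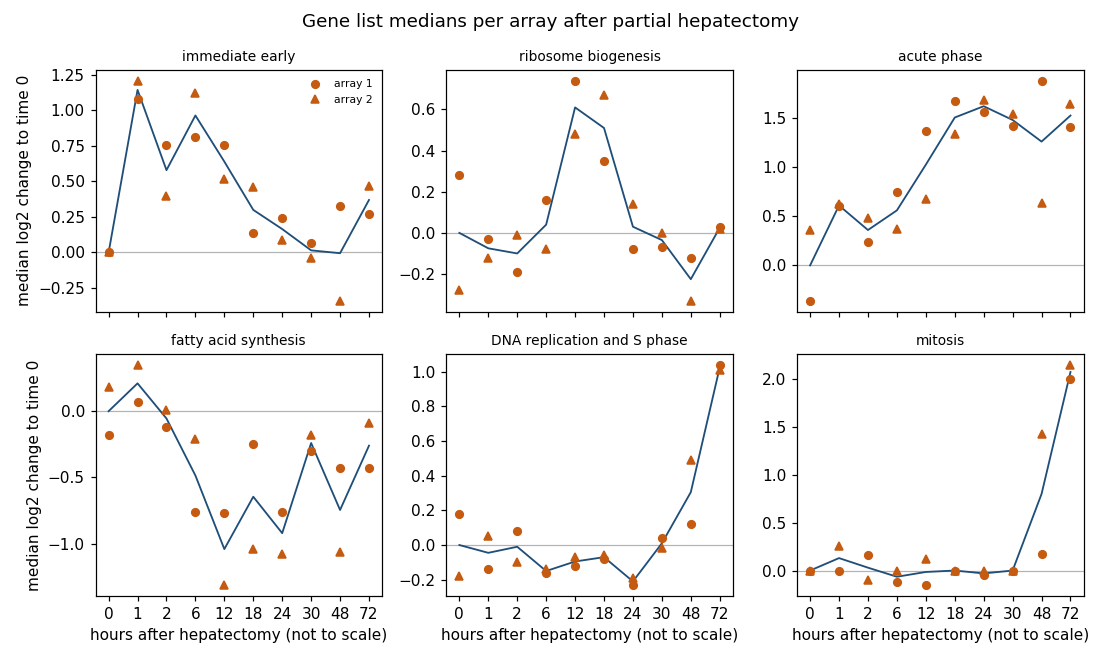
Median log2 change to time 0 of 6 gene lists (vertical axis) at time 0 and 9 times after hepatectomy (horizontal axis, hours, not to scale); lines are means of 2 arrays, circles the first and triangles the second array. The median of the mitosis list over its 28 members was 2.11 at 72 h, and that of the cholesterol list, not drawn, was -1.04 at 12 h.

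Igfbp1, G6pc and Pdk4 were among the genes raised at 1 to 6 h. Igfbp1, which encodes a binding protein of insulin-like growth factors, rose 44.4-fold over 1 to 6 h (log2 5.47 ± 0.40, 6 arrays against 2, adjusted p = 1.15e-07), from 144.2 ± 141 at time 0 to 5952 ± 804 at 1 h. The arrays of time 0 differed in this gene (44.8 and 243.6), and its log2 rise was 4.42 without the first and 6.52 without the second. G6pc, the catalytic subunit of glucose-6-phosphatase, rose by 3.79 ± 0.41 and read 4739 ± 885 at 1 h. By 12 h G6pc lay below its time 0 level (194.3 ± 59.2) at -21.79 ± 46.1 and was lowered there, by an amount that depends on the constant added. Pdk4, which spares glucose by inhibiting pyruvate dehydrogenase, rose by 3.21 ± 0.38 (adjusted p = 3.47e-05) and was highest at 6 h (1549 ± 602, against 46.39 ± 0.592 at time 0), and Ppp1r3g rose by 3.81 ± 0.29.

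Immediate early genes moved with them. Jun, a subunit of the transcription factor AP-1, went from 68.35 ± 26.7 to 852.3 ± 41.3 at 1 h and was raised over 1 to 6 h (2.76 ± 0.26, adjusted p = 2.31e-06). So were Dusp1 (2.74 ± 0.24), Btg2 (2.57 ± 0.21), Atf3 (3.21 ± 0.32) and Myc (1.60 ± 0.24, adjusted p = 0.000479). Fos read 811.8 ± 11.2 at 1 h against 58.98 ± 16.5 at time 0. Its rise over 1 to 6 h (2.19) was not called without either array of time 0 (2.42 and 1.96). Egr1 was not called in any of the 3 phases. Of the 24 measured immediate early genes 9 were raised, 0 lowered and 15 not called (14 raised when adjusted over the list alone, median 0.81, camera adjusted p = 8.69e-31, and 0.00186 with an estimated correlation). The list had 10 raised members at 1 h, 8 at 2 h, 9 at 6 h and 6 at 12 h. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose 8.38-fold (3.07 ± 0.25, adjusted p = 4.01e-07) and reached 962.2 ± 139 at 12 h from 42.83 ± 13.4. Of 11 measured p53 targets 2 were raised (2 when adjusted over the list alone, median 0.01, mean 0.45, adjusted p = 0.0599, but an upward shift in fry, 0.000143).

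Falls over 1 to 6 h were fewer. The nuclear noncoding RNA Neat1 fell by 2.03 ± 0.28 (adjusted p = 0.000182, -1.10 with the mean of its probe sets), and Derl3 by 2.09 ± 0.32 (-1.38 with an added constant of 64). The lipogenic genes Mid1ip1 (-1.51, not called without the first array of time 0, -1.08) and Elovl6 (-1.04, not called without that array, -0.70, or without the first array of 1 h, -0.94, of 2 h, -0.99, or of 6 h, -0.95, or with the mean of its probe sets, -0.72) also fell. In all, 126 genes were raised and 46 lowered, 87 and 22 of them at least 2-fold, and 104 were called (93 raised, 11 lowered) without the first array of time 0. A limma fit of only these 8 arrays called 81 genes (68 raised, 13 lowered).

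Several lists of hepatocyte metabolism shifted upward in the same hours while few single genes were called. Urea cycle and amino acid catabolism had 1 raised member of 21 (8 raised and 1 lowered over the list alone, median 0.49, adjusted p = 1.68e-09, 0.273 with an estimated correlation), and gluconeogenesis and glycogen 2 of 13 (3 over the list alone, median 0.37, adjusted p = 3.38e-07, 0.273 with an estimated correlation). The cytochrome P450 list had 0 of 21 called in limma (1 raised over the list alone, median 0.57, adjusted p = 2.91e-08, 0.273 with an estimated correlation, 0.0779 after quantile normalization). Acute phase had 3 of 23 raised (6 over the list alone, adjusted p = 2.91e-08, 0.397 with an estimated correlation) and fatty acid oxidation and ketogenesis 1 of 17 raised (1 over the list alone, adjusted p = 0.000367, 0.441 with an estimated correlation, 0.136 after quantile normalization). Bile acid synthesis and transport (median 0.35, adjusted p = 6.75e-05, 0.397 with an estimated correlation) and the secreted plasma proteins (median 0.41, adjusted p = 5.42e-05, 0.472 with an estimated correlation) shifted up, and limma called 0 members of either (0 over the list alone). Cholesterol synthesis shifted down with 0 of 16 called (1 lowered over the list alone, median -0.30, adjusted p = 0.00021, 0.441 with an estimated correlation). S100a8 (2.04 ± 0.28) and S100a9 (1.84 ± 0.25), proteins of neutrophil granules, were the raised members of the blood progenitor, neutrophil and megakaryocyte list (2 of 20, 3 over the list alone, adjusted p = 0.00549, 0.21 with an estimated correlation).

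Several of these shifts ended without a single array of time 0. Without the first, the adjusted p was 0.304 for acute phase, 0.0852 for cytochrome P450, 0.0649 for gluconeogenesis, 0.0852 for fatty acid oxidation and 0.577 for plasma proteins, and without the second 0.0708 for cholesterol synthesis and 0.0795 for blood progenitors. Ribosome biogenesis (0 of 26 genes called in limma, adjusted p = 0.726) shifted up without the first array of time 0 (0.0172) and down without the second (0.0036). Quantile normalization turned the sign of the plasma protein shift (adjusted p = 0.928). Circadian clock genes went both ways, with 3 raised and 2 lowered of 18 (6 and 4 over the list alone) and no shift in camera (adjusted p = 0.941): Cry1 went from 60.49 to 225 ± 47 at 2 h.

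Acute phase genes rose at 12 to 30 h. Lcn2, an iron-binding acute phase protein, rose 31.2-fold (log2 4.96 ± 0.39, 8 arrays against 2, adjusted p = 1.43e-07) and went from 232.4 ± 18.5 at time 0 to 8917 ± 169 at 18 h. The serum amyloid genes Saa3 (4.0 ± 0.48), Saa2 (3.30 ± 0.25, adjusted p = 1.43e-07) and Saa1 (2.46 ± 0.21) rose too. Saa1 had fallen at 2 h to 566.5 ± 6.45 from 1765 ± 286, a fall not called without the second array of time 0 (-1.44) or without ambiguous probe sets (-1.45), and read 10140 ± 150 at 30 h. Nnmt, a nicotinamide methyltransferase, rose 17.7-fold (4.14 ± 0.47) and the metalloreductase gene Steap4 by 2.32 ± 0.26 (adjusted p = 1.51e-05). Of 23 acute phase genes 17 were raised, 0 lowered and 6 not called (23 raised over the list alone, median 1.34, adjusted p = 1.59e-34, 0.0628 with an estimated correlation). Socs3, which damps interleukin 6 signalling, was raised at 12 h (2.16 ± 0.31, adjusted p = 0.000109).

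Lipogenesis fell in the same window. Pnpla3, a lipid droplet protein, fell by 2.20 ± 0.20 (adjusted p = 1.66e-06), from 330.7 ± 70.9 to 43.36 ± 19.4 at 24 h. The lipogenic transcription factors Mlxipl (-1.49 ± 0.21) and Srebf1 (-1.68 ± 0.27) and the elongase Elovl6 (-1.76 ± 0.22, -1.17 with the mean of its probe sets) fell with it. Fatty acid synthesis had 0 raised, 7 lowered and 9 not called of 16 members (9 lowered over the list alone, median -0.76, adjusted p = 1.6e-09, 0.24 with an estimated correlation), with 8 lowered at 12 h, 5 at 18 h, 7 at 24 h and 1 at 30 h. The steroid dehydrogenase gene Hsd3b5 fell by 2.40 ± 0.33 (adjusted p = 0.000138) and the succinate receptor gene Sucnr1 was lowered too (-2.37 ± 0.35). Cyp7a1, the first enzyme of bile acid synthesis, went from 445.2 ± 256 to 66.17 ± 0.942 at 12 h and 572.3 ± 320 at 30 h. Its fall over the phase (-1.68) was not called without the first array of time 0 (-1.08) and was -2.28 without the second. Nr0b2, a repressor of Cyp7a1, was itself lowered at 12 h.

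Ribosome biogenesis had its rise at 12 and 18 h, with 11 and 7 of 26 members raised there and 0 at 24 h in the same limma fit. Over 12 to 30 h 6 were raised and 0 lowered (8 raised over the list alone, median 0.22, adjusted p = 0.000749, 0.551 with an estimated correlation). The nucleolar proteins Npm1 and Ncl read 1339 ± 241 and 783.5 ± 11.9 at 18 h, from 676.4 ± 14.2 and 390.3. Neither call stood without the second array of 18 h (0.77 and 1.00), and that of Ncl ended without the second array of time 0 (0.79). The list's shift ended without the second array of time 0 (adjusted p = 0.394). No cell cycle gene of the lists was raised by then. Of 28 mitosis genes limma called 0 (adjusted p = 0.836, 0 over the list alone, median 0.04, mean -0.05, direction down). Of 29 genes of DNA replication and S phase 0 were raised and 3 lowered (3 over the list alone, adjusted p = 0.0615). Ccnd1, which encodes cyclin D1, was not raised in any phase and read 240.4 ± 94.8 at 18 h against 653.7 ± 188 at time 0. That fall was not called without the first array of time 0 (-1.12) or the second of 18 h (-1.02).

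Smaller shifts over 12 to 30 h were spread over many functions. Immediate early genes had 2 raised members of 24 (4 over the list alone, adjusted p = 0.00188, 0.489 with an estimated correlation). Heat shock and unfolded protein response had 2 raised of 18 (2 over the list alone, median 0.36, adjusted p = 0.0104, 0.583 with an estimated correlation, 0.12 without the first array of time 0, 0.275 after quantile normalization), with Dnajb9 at 1.51, not called without the first (1.55) or second (1.48) array of time 0. Extracellular matrix remodelling and growth factors had 3 raised and 1 lowered of 21 (3 and 1 over the list alone, adjusted p = 0.0212, 0.489 with an estimated correlation, 0.0541 without the first array of 24 h). Plasma proteins shifted up with 0 of 22 called in limma (0 over the list alone, median 0.28, adjusted p = 0.00449, 0.602 with an estimated correlation, 0.831 without the first array of time 0, and of the other sign after quantile normalization, 0.264). Of 24 genes of stellate cells and mesenchyme 2 were raised and 3 lowered (4 and 4 over the list alone, adjusted p = 0.519), and of 17 of endothelium 1 and 2 (1 and 2, 0.118). Of 25 erythroid genes 0 were raised and 2 lowered (0 and 4, median 0.02, mean -0.07, 0.519). Of 18 clock genes 1 was raised and 3 were lowered (2 and 6, 0.0505), among them Tef (-1.14 ± 0.20, -0.61 with the mean of its probe sets).

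Downward shifts of the bile acid, gluconeogenesis and cholesterol lists at 12 to 30 h depended on many single arrays. Bile acid synthesis and transport had 2 lowered of 20 (4 over the list alone, adjusted p = 0.028, 0.602 with an estimated correlation), and the adjusted p was 0.0582, 0.0815 and 0.134 without the second array of 12 h, 18 h or time 0. Gluconeogenesis had 3 lowered of 13 (3 over the list alone, 0.0425, 0.602 with an estimated correlation) and read 0.0678, 0.0815, 0.0826, 0.0944 and 0.971 without the first array of 30 h, the second of 18 h, the first of 24 h, the second of 12 h or the second of time 0. Cholesterol synthesis had 1 lowered of 16 (1 over the list alone, 0.0425, 0.653 with an estimated correlation) and read 0.0635, 0.0788, 0.0957, 0.175 and 0.273 without the second array of 12 h, the second of 30 h, the first of 24 h, the second of 18 h or the second of time 0. Blood progenitors, neutrophils and megakaryocytes had 2 raised of 20 (S100a8 and S100a9, 4 over the list alone, 0.0384, 0.399 with an estimated correlation) and read 0.179 among genes in the upper 50% by mean and 0.0505, 0.0507, 0.0672, 0.0755 and 0.12 without the first array of time 0, the second of 12 h, the second of 18 h, the first of 24 h or the second of time 0. Over all genes 463 were raised and 382 lowered (289 in all at least 2-fold), with 355 (248 raised, 107 lowered) without the first and 369 without the second array of time 0. There were 1300 and 1301 without the first and second array of 48 h, which enter only through the shared estimate of spread. A limma fit of only these 10 arrays called 95 genes.

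**Figure D2:**
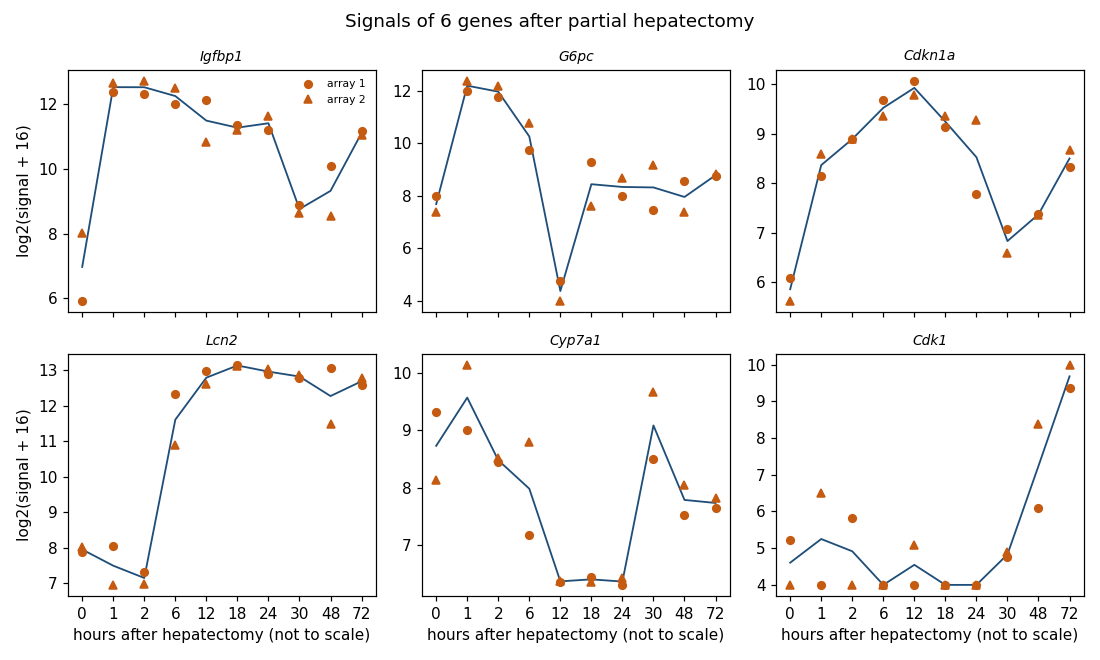
Intensity of 6 genes as log2(value + 16) (vertical axis) at time 0 and 9 times after hepatectomy (horizontal axis, hours, not to scale). Lines are means of the log2 values of 2 arrays, circles the first and triangles the second array. On the deposited scale Cdkn1a averaged 962.2 at 12 h, 99.63 at 30 h and 348.8 at 72 h, and Cdk1 averaged 822.4 at 72 h.

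Cell division genes rose at 48 to 72 h. Pcna, the sliding clamp of DNA polymerases, rose by 1.27 ± 0.17 (4 arrays against 2, adjusted p = 0.000182), from 245.9 ± 47.2 at time 0 to 356.8 ± 5.88 at 48 h and 1040 ± 149 at 72 h. Rrm2, a subunit of ribonucleotide reductase, rose by 3.04 ± 0.46 (3.69 and 2.38 without the first and second array of time 0) and Stmn1, a regulator of microtubules, by 2.91 ± 0.48. Cdk1, the mitotic kinase, went from 0.6733 ± 28.7 to 822.4 ± 255 at 72 h (3.85 ± 0.57 over the phase, adjusted p = 0.000471, 4.46 and 3.25 without the first and second array of time 0) and Birc5 from -10.1 ± 3.57 to 374.8 ± 89.2 (3.59 ± 0.40), sizes that depend on the constant added. Of 28 mitosis genes 19 were raised, 0 lowered and 9 not called (23 over the list alone, median 1.45, adjusted p = 2.67e-34, 0.0244 with an estimated correlation). Of 29 genes of DNA replication and S phase 13 were raised, 1 lowered and 15 not called (17 and 1 over the list alone, median 0.72, 4.13e-14, 0.0244 with an estimated correlation). At 72 h alone 22 mitosis and 18 S phase genes were raised, at 48 h alone 4 and 3. The median of the mitosis list was 0.17 and 1.43 on the arrays of 48 h and 2.00 and 2.15 on those of 72 h. The number of its genes above both arrays of time 0 was 18 and 25 at 48 h and 27 on each array of 72 h, but also 19 on the second array of 1 h and 20 on the first of 2 h, so the first array of 48 h showed no more than those.

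Acute phase genes and the cell cycle inhibitor Cdkn1a were raised at the same times. Lcn2 was still raised (4.52 ± 0.42, adjusted p = 3.94e-06), with Saa3 (4.24 ± 0.52), Saa2 (3.07 ± 0.28) and Nnmt (4.44 ± 0.51). Orm2 read 5928 ± 118 at 72 h against 236.5 ± 38.9 at time 0. Of the list 14 of 23 acute phase genes were raised, 0 lowered and 9 not called (20 over the list alone, median 1.32, 1.82e-33, 0.0244 with an estimated correlation). Cdkn1a, back at 99.63 ± 27.9 at 30 h, read 348.8 ± 60.7 at 72 h (2.08 ± 0.27 over the phase). Some macrophage genes were raised at these times, though not all of them for the first time. Timd4, a marker of resident Kupffer cells, went from 73.31 ± 0.553 to 278.7 ± 42 at 72 h (1.2 ± 0.19 over the phase, adjusted p = 0.000621). Of 17 macrophage and Kupffer cell genes 6 were raised, 0 lowered and 11 not called (9 over the list alone, median 0.46, 2.66e-06, 0.241 with an estimated correlation). Blood progenitors, neutrophils and megakaryocytes had 4 raised of 20, among them S100a8 (2.24 ± 0.29) and Prtn3 (2.70 ± 0.37) (6 over the list alone, median 0.25, 0.000919, 0.038 with an estimated correlation, 0.13 among genes in the upper 50% by mean).

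Hsd3b5 (-2.33 ± 0.36, adjusted p = 0.000578), Pnpla3 (-1.67 ± 0.22) and Igfbp3 (-1.57 ± 0.20) remained lowered at 48 to 72 h, as did Nr1d1, a repressor within the circadian clock (-1.75 ± 0.29, -1.07 with an added constant of 64, 134.2 ± 36.3 at time 0 and 17.48 ± 16.4 at 48 h). Fatty acid synthesis had 3 lowered of 16, 13 not called (8 over the list alone, median -0.56, 7.25e-08, 0.175 with an estimated correlation), and cholesterol synthesis shifted down with 0 of 16 called in limma (0 over the list alone, median -0.55, 1.17e-05, 0.315 with an estimated correlation). Plasma proteins had 1 raised of 22 (1 over the list alone, 0.000381, 0.571 with an estimated correlation, 0.265 without the first array of 48 h, 0.453 without the first of time 0 and 0.315 after quantile normalization). Extracellular matrix remodelling and growth factors had 4 raised and 1 lowered of 21 (6 and 1 over the list alone, 0.0389, 0.345 with an estimated correlation, 0.0887, 0.103 and 0.29 without the second array of 72 h, the first of time 0 or the first of 48 h, 0.0766 among genes in the upper 50% by mean).

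At 48 to 72 h camera called no shift of several other cell types. These were endothelium (0 of 17 called in limma, 0.165), bile duct epithelium (0 of 11, median 0.09, mean -0.00, 0.971), neighbouring organs (0 of 21, median -0.03, mean 0.01, 0.91) and lymphocytes (1 raised of 13, 0.301). Nor did it call hepatoblast genes (1 lowered of 16, 0.116), embryonic globins (0 of 3, 0.279), sex chromosome linked genes (0 of 4, median 0.03, mean -0.13, 0.697) or heat shock (1 raised of 18, 0.248). Adjusted over each of those lists alone, 0, 0, 0, 1 raised, 2 lowered, 0, 0, and 3 raised with 1 lowered were called.

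At 48 to 72 h 333 genes were raised and 107 lowered, 229 in all at least 2-fold; Lcn2, Pcna and Cdk1 were among the raised in the fit of all 32 arrays. A limma fit of only the 6 arrays of time 0, 48 h and 72 h called 0 genes, with 1165 at an unadjusted p under 0.05 (735 raised, 430 lowered), so the calls of this phase rest on the spread estimated over all groups. The total was 281 without the first and 239 without the second array of time 0, 1299 (487 raised, 812 lowered) without the first array of 48 h and 827 (689 raised, 138 lowered) without the second.

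Embryonic liver differed from unoperated adult liver in 10023 genes, 5543 raised and 4480 lowered. Cdkn1c, a cell cycle inhibitor of growing embryonic tissues, was 6.45 ± 0.15 (log2, 12 arrays against 2, adjusted p = 3.68e-18) higher, and Cd24a 6.5 ± 0.18. Igf2 lay between 3973 and 5285 in the embryo against 175.5 ± 43.2 at time 0. At the other end Ces1c, a carboxylesterase of mature liver, was 244-fold lower (-7.93 ± 0.23, adjusted p = 7.76e-17), and Akr1c6 (-7.71) was close behind. Cyp3a11 read 5560 ± 1130 at time 0 and 23.41 to 170 in the embryo, and Cps1, the first enzyme of the urea cycle, 4419 ± 1610 against 130.8 to 636.7.

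Most genes of the hepatocyte lists were lower in the embryo. All 21 measured cytochrome P450 genes were lowered (21 over the list alone, median -5.40, adjusted p = 5.26e-19), as were 19 of 20 genes of bile acid synthesis and transport (19 over the list alone, median -3.67, 1e-13). Urea cycle and amino acid catabolism had 20 lowered and 1 raised of 21 (the same over the list alone, 5.45e-13), and plasma proteins 19 lowered of 22 (20 over the list alone, 5.19e-11). For these 4 lists the adjusted p with an estimated correlation was 0.0232, 0.0397, 0.0753 and 0.113. Acute phase had 2 raised and 20 lowered of 23 (2 and 21 over the list alone, median -3.29, adjusted p = 8.52e-13, 0.1 with an estimated correlation).

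Carbohydrate, fat and clock genes shifted the same way. Gluconeogenesis had 2 raised and 11 lowered of 13 (adjusted p = 4.93e-05), fatty acid oxidation 0 and 12 of 17 (0.000251), fatty acid synthesis 1 and 14 of 16 (0.000115) and the clock 1 and 12 of 18 (0.000557). These counts were the same over each list alone, and the adjusted p with an estimated correlation was 0.178, 0.271, 0.194 and 0.0664. Liver transcription factors had 12 lowered and 7 not called of 19 (12 over the list alone, 1.85e-05, 0.0753 with an estimated correlation). Hnf4a read 213.8 to 570.3 in the embryo against 1122 ± 416 and Cebpa 107 to 351.7 against 958 ± 86. Cholesterol synthesis had 5 lowered and 11 not called of 16 (3 over the list alone, 0.0474, 0.557 with an estimated correlation). That shift ended without any of 8 arrays: either of 14.5 days, the second of 16.5, 12.5 or 10.5 days or of time 0, or the first of 13.5 or 11.5 days (0.0505 to 0.101).

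Red cell, progenitor and proliferation genes were higher. Of 25 erythroid genes 24 were raised and 1 not called (24 over the list alone, median 3.67, adjusted p = 2.13e-16, 0.00372 with an estimated correlation), and all 3 embryonic globins were raised (3 over the list alone, 0.000642, 0.0749 with an estimated correlation). DNA replication and S phase had 24 raised and 1 lowered of 29 (26 and 1 over the list alone, median 3.05, 3.06e-14, 0.0189 with an estimated correlation). Mitosis had 25 and 2 of 28 (25 and 2 over the list alone, median 4.05, 1e-13) and ribosome biogenesis 24 and 0 of 26 (25 and 0, median 1.72, 1.75e-09), both at 0.0753 with an estimated correlation. Pcna lay between 3608 and 6013 in the embryo and Ncl was 2.67 higher (1.60 with the mean of its probe sets). Hepatoblast and fetal liver genes had 12 raised, 2 lowered and 2 not called of 16 (the same over the list alone, median 2.05, 1.85e-05, 0.00949 with an estimated correlation). Afp was 5.87 higher, while Dlk1, at 2587 to 4277 in the embryo, was 6.08 higher but 0.45 and not called without ambiguous probe sets.

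Other cell types of the embryonic organ went both ways. Blood progenitors, neutrophils and megakaryocytes had 13 raised and 1 lowered of 20 (14 and 1 over the list alone, 0.000115, 0.0189 with an estimated correlation), and stellate cells and mesenchyme 17 and 4 of 24 (17 and 4, median 0.97, 0.0031, 0.0753 with an estimated correlation). Macrophages and Kupffer cells had 1 raised, 8 lowered and 8 not called of 17 (1 and 8 over the list alone, 0.0119, 0.431 with an estimated correlation). Endothelium (3 raised, 4 lowered of 17, 0.548), lymphocytes (4 and 5 of 13, 0.226), bile duct epithelium (1 and 3 of 11, 0.498) and neighbouring organs (6 and 4 of 21, 0.893) showed no shift in camera. Nor did heat shock (6 and 7 of 18, 0.872), immediate early genes (8 and 6 of 24, 0.851) or p53 targets (6 and 2 of 11, 0.34). In each of these lists the counts were the same over the list alone. With fry, however, lymphocytes shifted down (adjusted p of fry 0.000233), and neighbouring organs (0.000504) and p53 targets (1.02e-06) shifted up. For endothelium, bile duct epithelium, heat shock and immediate early genes the adjusted p of fry was 0.243, 0.0508, 0.571 and 0.613. Extracellular matrix remodelling had 7 and 6 of 21 (the same over the list alone, median -0.22, mean 0.19, direction down, adjusted p = 0.917, fry gave the other sign, 0.00363). Sex chromosome linked genes had 1 raised of 4 (1 over the list alone, 0.625, but an upward shift in fry, 0.00257). Xist was not called in any of the 6 comparisons. The raised gene was therefore Y-linked, since the other measured members are Eif2s3y, Kdm5d and Uty. Sex may thus differ between the embryonic arrays and the females of time 0.

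Plasma protein genes rose from 10.5 to 16.5 days. Apoh, which encodes a plasma glycoprotein, rose by 1.08 ± 0.05 (log2 per day over 12 arrays), and Ahsg, a fetal plasma protein, went from 4.592 ± 1.76 at 10.5 days to 3375 ± 32.2 at 16.5 days. Alb went from 1249 ± 414 at 10.5 days to 6246 ± 265 at 11.5 days and 8673 ± 31.2 at 16.5 days, against 7834 ± 524 at time 0. Plasma proteins had 19 raised and 3 not called of 22 (20 over the list alone, median 0.37, adjusted p = 8.71e-16, 0.109 with an estimated correlation) and acute phase 17 raised and 6 not called of 23 (17 raised and 1 lowered over the list alone, 1.42e-10, 0.221 with an estimated correlation). Urea cycle and amino acid catabolism had 15 raised and 1 lowered of 21 (16 and 1 over the list alone, 4.75e-07), gluconeogenesis 9 raised of 13 (9, 1.1e-05) and bile acids 10 of 20 (13, 2.77e-05), each at an adjusted p of 0.221 with an estimated correlation. Cholesterol synthesis had 6 raised of 16 (8 over the list alone, 0.00329) and fatty acid oxidation 8 of 17 (11, 0.0033), both at 0.425 with an estimated correlation. Fatty acid synthesis had 4 raised of 16 (4 over the list alone, 0.202) and liver transcription factors 5 raised and 2 lowered of 19 (5 and 2, 0.48). Rises within hepatocytes were not separated from a growing share of hepatocytes in the organ.

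Erythroid genes rose over development and embryonic globins fell. Rhag, a red cell membrane protein, went from 130.7 ± 12.4 at 10.5 days to 1953 ± 96.9 at 16.5 days, and Klf1 from 342.4 to 3325, whereas the embryonic globins Hbb-bh1 (5941 ± 374 to 555.9 ± 12.4) and Hba-x (7414 ± 107 to 1610 ± 62.1) went down. All 25 erythroid genes were raised over development (25 over the list alone, median 0.50, adjusted p = 1.24e-28, 0.000148 with an estimated correlation) and all 3 embryonic globins lowered (3 over the list alone, median -0.44, 0.000417, 0.104 with an estimated correlation). Macrophages and Kupffer cells had 13 raised and 4 not called of 17 (14 over the list alone, 1.19e-09, 0.109 with an estimated correlation), with Cd5l, a protein of tissue macrophages, going from 6.537 ± 6.5 to 1079 ± 38.9. Blood progenitors had 11 raised and 1 lowered of 20 (13 and 1, 3.25e-06, 0.00667 with an estimated correlation) and lymphocytes 6 raised of 13 (6, 0.0264, 0.221 with an estimated correlation, 0.0648 without the first array of 10.5 days, 0.98 among genes in the upper 50% by mean). DNA replication and S phase had 14 raised and 2 lowered of 29 (15 and 2, 0.00329, 0.297 with an estimated correlation).

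Mesenchymal and heart genes went down over the same days. Mdk, a growth factor of embryonic mesenchyme, fell by 0.72 ± 0.03 per day. Stellate cells and mesenchyme had 4 raised, 14 lowered and 6 not called of 24 (5 and 14 over the list alone, median -0.15, adjusted p = 4.8e-05, 0.0495 with an estimated correlation). The heart muscle genes Myl7 (-0.82 per day) and Myh7 (-0.96 ± 0.07, -1.63 with an added constant of 1) were high at 10.5 days (4203.3 and 2734.1, and 2894.4 and 947.1, on its arrays), near baseline at 11.5 days and again above it at 12.5 days (Myl7 127.2 and 1148.7, Myh7 274.6 and 1045.5 on its arrays). Neighbouring organs, the list fixed for such signals, had 4 raised and 6 lowered of 21 (the same over the list alone, median 0.01, mean -0.11, 0.0879). Hepatoblast genes had 1 raised and 6 lowered of 16 (the same over the list alone, 0.0336, 0.167 with an estimated correlation, 0.107 without the first array of 10.5 days, 0.0581 among genes in the upper 50% by mean). Ribosome biogenesis had 1 raised and 2 lowered of 26 (1 and 1 over the list alone, 0.0453, 0.564 with an estimated correlation), with 0.053, 0.102, 0.0541, 0.0596 and 0.287 without the first array of 11.5 days or the second of 16.5, 14.5, 12.5 or 10.5 days. Cytochrome P450 had 4 raised of 21 (4 over the list alone, 0.0423, 0.564 with an estimated correlation), with 0.0511, 0.0541, 0.0544 and 0.0663 without the first array of 11.5 days or the second of 14.5, 16.5 or 10.5 days, and 0.15 among genes in the upper 50% by mean.

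Over development 2947 genes, Ahsg and Rhag among them, were raised and 2081, Mdk among them, lowered (2308 and 2492 after quantile normalization, 2433 and 2648 after array median centring). An F test over the 6 stages called 3789 (20.8%).

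**Figure D3:**
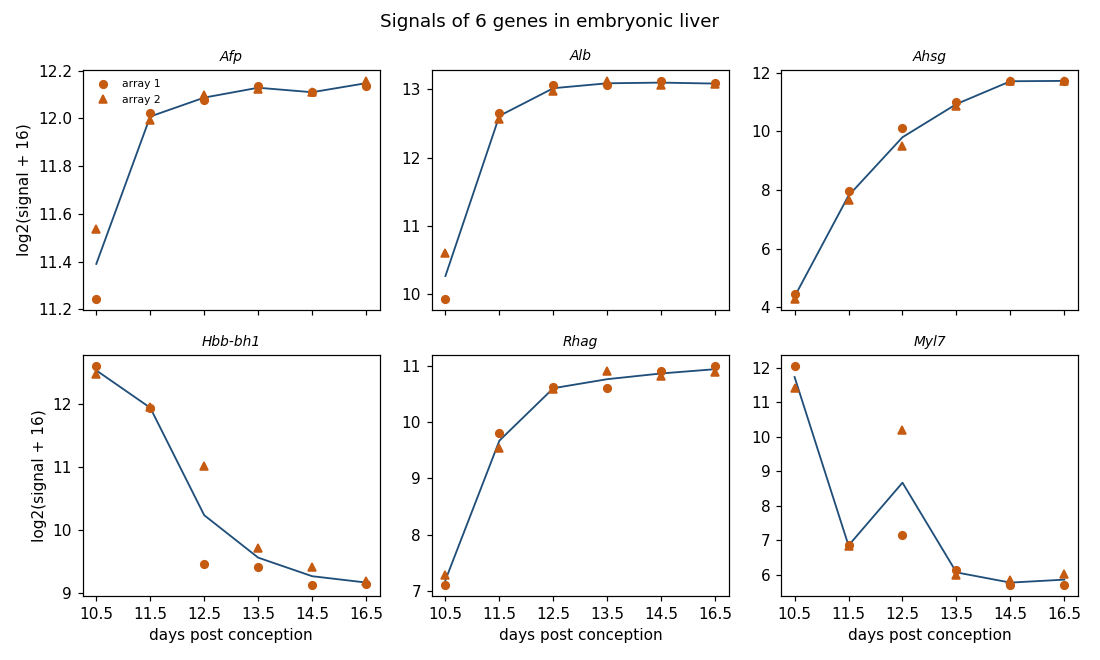
Intensity of 6 genes as log2(value + 16) (vertical axis) in embryonic liver by day post conception (horizontal axis). Lines are means of the log2 values of 2 arrays, circles the first and triangles the second array. On the deposited scale Rhag averaged 130.7 at 10.5 days and 1953 at 16.5 days, and Hbb-bh1 5941 and 555.9.

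Proliferation genes were higher in whole embryonic liver than in whole liver at 48 to 72 h. Against 48 to 72 h Pcna was 8.09-fold higher in the embryo (log2 3.02 ± 0.11, 12 arrays against 4) and Cdk1 2.46 ± 0.38 higher. DNA replication and S phase had 26 raised and 1 lowered of 29 (26 and 1 over the list alone, median 2.26, adjusted p = 6.14e-12, 0.0394 with an estimated correlation). Mitosis had 25 and 2 of 28 (25 and 2, median 2.46, 1.73e-08, 0.177 with an estimated correlation) and ribosome biogenesis 25 and 0 of 26 (25 and 0, 9.59e-10, 0.0798 with an estimated correlation). Cdkn1c (6.71 ± 0.11, adjusted p = 4.27e-21), Afp (6.37 ± 0.17) and Rhag (6.01 ± 0.10, 9.97 with an added constant of 1) were higher in the embryo, and the acute phase genes Lrg1 (331-fold, -8.37 ± 0.24), Orm1 (-7.95 ± 0.18) and Saa1 (-7.35 ± 0.15) lower. Acute phase had 0 raised and 22 lowered of 23 (22 over the list alone, median -5.87, 4.76e-17, 0.0798 with an estimated correlation). Cytochrome P450 had 21 of 21 lowered (21, 2.07e-17, 0.0394 with an estimated correlation) and macrophages 1 raised and 14 lowered of 17 (1 and 14, 3.3e-05, 0.177 with an estimated correlation). Erythroid genes had 24 raised and 1 lowered of 25 (24 and 1, median 4.11, 3.21e-14, 0.00614 with an estimated correlation). Over all genes 6425 were raised and 5595 lowered. Here and against time 0, differences within hepatocytes were not separated from a different share of other cells in the organ. The regenerating side also averages 2 unlike times. Against time 0 the mitosis median was 0.17 and 1.43 on the arrays of 48 h and 2.00 and 2.15 on those of 72 h.

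Rrm2, Stmn1, Cdk1, Birc5 and Top2a were raised both at 48 to 72 h and in the embryo, each against time 0. The shared raised genes numbered 207, or 62.2% of the 333 raised late, where independent lists would share 101.5, and 32 of the 57 measured members of the mitosis and S phase lists were among them (19 and 13). The shared lowered genes, with Hsd3b5, Neat1 and Nr1d1 among them, numbered 57, where independent lists would share 26.35; 3 belonged to fatty acid synthesis. Of the 207, 175 differed between embryo and 48 to 72 h and 159 of them were higher in the embryo, and of the 57 lowered 39 differed and 2 were higher in the embryo. Both comparisons use the same 2 arrays of time 0, which were not split between them, as that would leave a single array for each. Groups simulated without change gave 0 shared genes of either kind in 20 draws, but a correlation of 0.756 between the comparisons (0.183 observed) and a covariance of 0.0399 (0.0799 observed). In those draws the embryo was unchanged too, so few genes could be called in either comparison. The 0 is therefore no measure of what an unchanged 48 to 72 h group would share with a changed embryo, which was not simulated. Part of the excess may come from the shared controls. Shared raised genes numbered 101 and lowered ones 32 and 31 when the second (raised) and the first or second (lowered) array of time 0 was left out. Without the first array of 48 h they were 324 and 327, and 323 raised without the second.

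Of the acute phase list 11 genes, and of the erythroid list 2, were called in opposite directions at 48 to 72 h and in the embryo, each against time 0. Lrg1, Orm1 and Steap4 were raised at 48 to 72 h and lowered in the embryo, like 71 genes in all, whereas 2 of the 23 acute phase genes were raised in both and 17 rose over the embryonic days. The calls of Lrg1 (1.5) and Orm1 (1.08) at 48 to 72 h ended without the first array of time 0, and quantile normalization brought Orm1 to 0.91. Tfrc, the transferrin receptor, fell at 48 to 72 h (-1.55 ± 0.28, not called without the first array of time 0, -1.18, or with the mean of its probe sets, -0.95) and was 2.56 ± 0.24 higher in the embryo, as in 27 genes. At 12 to 30 h 223 genes were raised as in the embryo (141.1 for independent lists) and 227 lowered (94.06), and at 1 to 6 h 52 (38.39) and 18 (11.33). Opposite calls numbered 107 (114) and 76 (116.4) at 12 to 30 h, and 42 (31.03) and 19 (14.01) at 1 to 6 h, so the excess at 1 to 6 h went both ways. These comparisons share the arrays of time 0 too, so independent lists are not what an unchanged phase would share with the embryo. That number was not simulated for any phase.

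**Figure D4:**
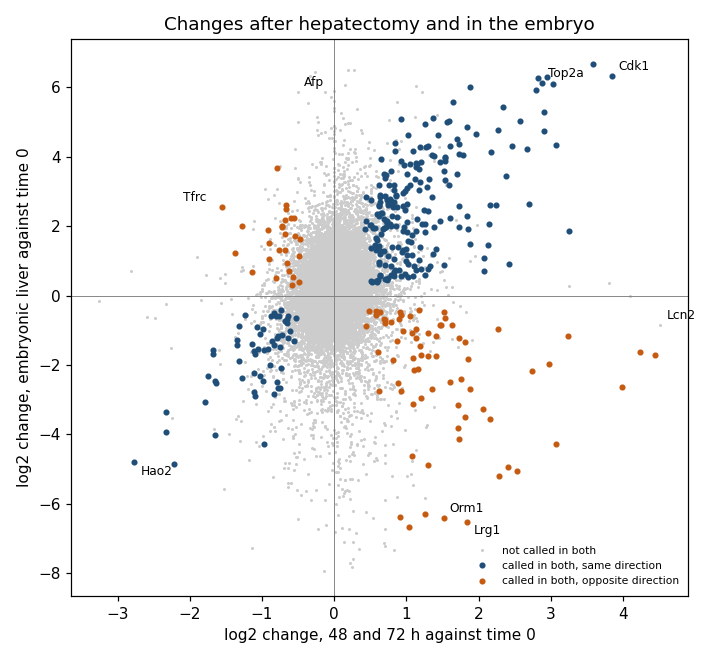
Log2 change of each gene at 48 to 72 h (horizontal axis) and in the embryo (vertical axis), both against time 0; points are genes. The correlation over 18194 genes was 0.183.

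Late regeneration and the course of development, which share no array, showed no correlation across genes that passed the test. The log2 change at 48 to 72 h, in which Pcna and Lcn2 rose, correlated with the change per day of the embryo at r = 0.0313 (exact permutation of the 6 stages over 720 orders, p = 0.385, adjusted p = 0.641 over 12 relations, smallest possible p 0.00139). The rank correlation was 0.00499 (p = 0.91 in the same exact permutation). Without the cell cycle lists r was 0.0253. For 1 to 6 h r was 0.108 (exact permutation p = 0.35) and for 12 to 30 h -0.0162 (exact permutation p = 0.685). The sign turned without the first array of time 0 (-0.0292) or the first of 48 h (-0.0449).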

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

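In this part the genes Gadd45a and Atxn7l3 and the tests that led to them were chosen only after the result was seen.

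Against time 0, 71 genes were raised at 48 to 72 h and lowered in the embryo, and 27 the other way. That they also differed between embryo and 48 to 72 h follows from this choice of genes and adds no evidence. Lower in the embryo than in adult liver does not mean falling over development: 17 of 23 acute phase genes rose over the embryonic days. Among the 71 were 11 of 23 acute phase genes, such as Orm1 and Steap4, and 2 macrophage genes; among the 27 were 2 erythroid genes, such as Tfrc. Independent lists of the same sizes would hold 82 and 32.6 such genes, but the shared arrays of time 0 make opposite calls rarer than that, and how rare was not simulated.

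Within regeneration, 1 gene was raised at 1 to 6 h and lowered at 12 to 30 h: Gadd45a, a stress gene, with changes of 1.10 and -1.34. It went from 135.1 ± 7.23 at time 0 to 672.2 ± 15.7 at 6 h and 23.12 ± 7.6 at 18 h. In the other direction 1 gene, Atxn7l3, had changes of -1.98 and 1.24. A difference between the phases follows from the choice of these genes. No cause was tested for either gene.

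Probe sets without a listed gene also changed: 64 of 9160 at 48 to 72 h (0.699%, against 2.42% of named genes), 47 of them raised, and 3087 between embryonic and adult liver (33.7%, against 55.1%), 1073 of them raised. What they measure was not analysed here.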

How the results depend on the processing

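In this part the fits with the second arrays of 12 h and 48 h left out together and with array weights were chosen only after the result was seen. Of 17376 values for 389 gene results 16757 gave the same call, 610 a weaker, 8 a stronger and 1 a reversed one. For 6786 values of 174 list results these numbers were 6530, 154, 97 and 5. Many of these genes were named for large changes or small p, and those whose call depended on few settings were preferred. Their agreement is therefore high by choice and does not measure how calls of other genes hold. The reversed gene was Cep112 at 12 to 30 h (-0.14 without _x_at and _s_at probe sets). The reversed lists were plasma proteins at 1 to 6 h (0.928) and 12 to 30 h (0.264) and urea cycle at 12 to 30 h (0.00215) after quantile normalization, extracellular matrix in the embryo with fry (0.00363), and ribosome biogenesis at 1 to 6 h without the first array of time 0 (0.0172; 0.0036 to 0.992 over single arrays left out).

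Calls at 2-fold or more gave 109 genes at 1 to 6 h, 289 at 12 to 30 h, 229 at 48 to 72 h, 4574 in the embryo, 2041 in the trend, 4585 for embryo against 48 to 72 h, 1439 in the F test, and 95 raised and 24 lowered in both. With only the groups compared limma called 81, 95 and 0 in the 3 phases (1165 at an unadjusted p under 0.05 in the last) and 1562 in the F test. Only genes in the upper 50% by mean gave 283 at 48 to 72 h, 5765 in the embryo, 2847 in the trend and 6612 for embryo against 48 to 72 h. Quantile normalization gave 702 at 48 to 72 h (472 raised, 230 lowered), 141 lowered in both and a correlation of -0.00394 (exact permutation p = 0.893); an added constant of 64 gave 96 lowered in both. An estimated correlation left 18 of 85 list shifts. Without the second arrays of 12 h and 48 h 294, 1606 and 978 genes were called in the phases and 391 raised in both; array weights gave 181 at 48 to 72 h, 93 raised and 16 lowered in both, but weigh the 2 arrays of a group alike. The cause was not tested for these moves. Replicate number as a replicate block gave 164, 812 and 443 genes in the phases, 9975 in the embryo and 85 list shifts; the median correlation of replicate differences over 120 pairs of groups was -0.0062, with a lowest of -0.359, a highest of 0.555 and 17 over 0.1, and the second array of 48 h matched the second of 12 h best (0.859), so some arrays of the same number may share more than the number.

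Over single arrays left out, totals ran from 104 to 246 at 1 to 6 h, 355 to 1301 at 12 to 30 h, 239 to 1299 at 48 to 72 h, 7930 to 10496 in the embryo, 3665 to 5629 in the trend, 10815 to 12169 for embryo against 48 to 72 h and 2703 to 6387 in the F test. With only the 6 arrays of time 0, 48 h and 72 h left out in turn, raised in both ran from 101 to 324 and lowered in both from 31 to 327. Over all 32 arrays list shifts ran from 78 to 94 and the correlation from -0.0449 to 0.107, with -0.0292 without the first array of time 0. The arrays of time 0 and 48 h set these ends, save at the low end of the trend (second of 16.5 days) and of the F test (second of 2 h) and at both ends of embryo against 48 to 72 h.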

Other observations

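In this part the tests of array noise, heart tissue, dilution, hour of day and a single noisy array were chosen only after the result was seen; those of other splits of the arrays, RNA degradation and RNA of another cell type were set before.

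Circadian clock genes were called more often than genes as a whole at 1 h, with 4 raised and 2 lowered of 18 when 86 of 18194 genes were called, and a mean absolute change of 0.82 against 0.25 over all genes. At 30 h the mean absolute change was 0.32 against 0.23. Dbp, not called at 1 h, went from 531.5 ± 66.6 at time 0 to 222.5 ± 8.39 at 1 h, Tef from 331.8 ± 3.36 to 67.63 ± 18.6 at 12 h, and Nr1d1 from 134.2 ± 36.3 to 17.48 ± 16.4 at 48 h. The macrophage receptor gene Marco read 110.3 at time 0, 508.9 ± 0.35 at 18 h and 548.8 ± 95.6 at 72 h, whereas its list had 1 raised and 2 lowered of 17 at 18 h and 7 raised at 72 h.

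Embryonic liver and liver at 48 to 72 h differed in more genes than other splits of the same arrays gave. In a model with 2 groups the real split of the 16 arrays called 10572 genes and the highest of the other splits 4018. Of 100 splits only 1, the real one, called as many. Every other split mixes embryonic with adult arrays, which the first principal component already separated. A lower count was thus fixed in advance, and the test cannot decide about chance. Age, operation and tissue source differ together here, sex may differ too, and no biological explanation was tested.

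The second array of 48 h held more Mki67, Top2a and Cdk1 and less acute phase RNA than the first. RNA of another cell type showed no rise: the highest median difference among 9 lists of other cell types was 0.06, for neighbouring organs. A larger share of other cells stays open, because this test did not set them against hepatocyte RNA. The plasma protein list was at -1.15, but bile duct epithelium at -0.04, erythroid genes at -0.07 and endothelium at -0.32. Macrophages (-0.69) and lymphocytes (-0.53) lay between. Array noise stays open. The mitosis difference of 1.30 lay at percentile 100 of 10000 random lists matched on level, but the list was picked for its difference and random lists lack the correlation of its members. RNA degradation met the bound set in advance. Both 3 prime over 5 prime ratios were the highest of the 20 adult arrays, at least 4.68 SD above the mean of the other 19. How much of the difference between the 2 arrays it accounts for stays open. Degraded RNA could lower the hepatocyte lists, but whether it could raise mitosis genes was not tested, and a difference in progress through the cell cycle between the pools was not tested either.

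Heart muscle genes were high at 10.5 days. An equal dilution of heart and endothelial cells as hepatocytes and red cells expand is argued against. The heart median changed by -0.61 ± 0.21 per day and the endothelium median by 0.06 ± 0.02, a difference of -0.67 ± 0.21. These slopes are straight lines, whereas the heart genes dropped by 11.5 days and were higher again at 12.5 days. Dilution of other cells stays open, since stellate cells and mesenchyme fell over development (median -0.15 per day, 14 lowered and 4 raised of 24). Heart tissue taken along in the dissection cannot be told apart from other sources: 4 of 6 heart genes were higher on both arrays of 10.5 than on both of 16.5 days, where 5 had been asked for. That bound was judged poor once the values were seen, because Tnnt2 stayed at 41.4 to 60.7 on all embryonic arrays, under the median of all values (74.6), and Nkx2-5 missed by 152.7 on the second array of 10.5 days against 169.6 on one of 16.5 days, whereas Myh6, Myh7, Myl7 and Actc1 met it. A candidate explanation is the closeness of heart and liver bud in small embryos, and the high values on the arrays of 12.5 days (Actc1 1957.7 and 4319.9) may have the same source.

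In the fit of all arrays the largest totals of changed genes, with Cd14 and Lcn2 among them, fell at 12 and 18 h (1593 and 1391). In fits of only the groups compared 72 h had the most (46, against 2 at 12 h and 27 at 18 h), and without the first array of 48 h that time had the most (3210). A single noisy array of 12 or 18 h stays open. With each of those 4 left out of the fit of all arrays, the lowest total at 12 or 18 h was 581, at 18 h without its second array. In the same fits the totals were 380 to 424 at 6 h and 548 to 568 at 72 h. The bound written for this test was the total at 6 h, and both times stayed above it in every one of these fits. The total at 72 h was not part of that bound, and it rests on both arrays of its time. The margin over 72 h is small and these totals have no measured spread, so the test cannot decide. Hour of day at harvest may add to the totals at 12 and 18 h, and it cannot be told apart from time after operation. The mean absolute change of the 18 clock genes was 0.59 at 12 h and 0.58 at 18 h but 0.68 at 24 h, where the hour would equal that of time 0 (18 h minus 24 h -0.11 ± 0.08, standard error over genes). The bound as first written would have argued against the hour of day, and the band of 2 standard errors that leaves it open was added after the values were seen.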
